A study of Mus musculus with 4 samples.

How the data were processed

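The samples were mouse alveolospheres, organoid co-cultures in which alveolar type 2 (AT2) cells, the surfactant-making stem cells of the alveolus, grew together with PDGFRα-positive lung fibroblasts, per the labels. AT2 cells had been isolated by their uptake of LysoTracker, a dye of acidic organelles such as lamellar bodies. In the knockdown group the paralogous transcriptional co-activators YAP and TAZ (genes Yap1 and Wwtr1) were knocked down in the fibroblasts alone with a doxycycline-inducible system. Both groups received 3 µg/ml doxycycline in the medium, starting on day 7, and were collected on day 14, so the drug itself did not differ between them. Each group had 2 libraries. The labels call these biological replicates but do not say that they came from separate animals or cultures, so p-values measure the spread between these libraries, which may be partly technical. The labels place all 4 libraries in 1 batch.

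Libraries were prepared with a 10x Genomics kit that reads RNA and open chromatin from the same cell, per the labels' protocols; the same protocol field also names a column-based RNA extraction, which is not a step of that kit. The deposited RNA matrix held whole-number counts of unique molecular identifiers (UMIs) per gene and cell, not normalised, for 45936 cells and 32285 genes, per the file headers and the values. The sums of the matrix equalled the UMIs and genes per cell that the authors deposited in 45936 of 45936 cells. The genome build was GRCm38 (mm10), per the submitters' processing notes; the aligner, the counter and the treatment of intronic reads are not given in the sources used here. The deposited cells had at most 35.0% mitochondrial UMIs, at least 402 genes and at least 533 UMIs, so cells outside these limits were not analysed here. The authors deposited the mitochondrial share of each cell as a percent, computed from its 13 mitochondrial genes. They also deposited counts of ATAC fragments per cell and a doublet enrichment ratio made from the ATAC data, with no further description in the file headers; these were used only to describe the cells. A further 51 deposited columns of cell values were not used. The chromatin profiles themselves were not analysed here.

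Cell classes were taken from the annotation the authors deposited, which has 15 classes over 27 clusters, with 8 cluster numbers missing from the sequence. Each cluster was checked against cell type markers. The class deposited as AT2 did not pass that check as a single class. Its clusters 19 and 23 carried fibroblast markers at 62.1% and 56.1% of the fibroblast level, with median depths of 9364 and 10070 UMIs and the highest ATAC doublet enrichment, and were left out of every class as mixed. Cluster 14 was led by the AT1 genes Clic5, Ager, Col4a3 and Akap5 and was used as AT1-like cells. Cluster 32 (170 cells) carried Scgb1a1 at 1425 CPM against 12.3 CPM in cluster 9, with Scgb3a1, Bpifa1 and Muc5b also higher. It is left unnamed, because its 21 cells of knockdown library 1 read 0 CPM of these 3 genes, and because most of its control and knockdown cells parted when all cells were clustered anew. Cluster 9 remained as AT2 cells, and the class deposited as cycling AT2 (cluster 20) was tested on its own. The epithelial compartment was the sum of these and the transitional epithelial class. The fibroblast compartment was all deposited fibroblast classes, smooth muscle, EMT-like and unknown mesenchymal cells; 143 mesothelial cells entered neither compartment.

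Cells are not replicates, so raw counts were summed per library and class and compared across the 4 libraries. The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM normalisation and its default filter on low counts, and p-values were adjusted by the Benjamini-Hochberg method; every adjusted p of a gene comes from it unless DESeq2 (1.42.0) or limma voom (limma 3.58.1) is named. A gene counted as changed at an adjusted p under 0.05. Classes were tested when every library held at least 50 of their cells. The difference between the fibroblast and the epithelial effect was tested as an interaction, with the library as a block. Levels are given as normalised CPM, scaled to the same total in each library, mean ± SD over the 2 libraries of a group. Log2 fold changes are knockdown minus control and carry their SE.

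Gene lists for 23 pathways were compared with all other genes by camera in limma with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. No list was called by either of these: the smallest adjusted p in fibroblasts was 0.675 with an estimated correlation and 0.107 by fry, against 0.881 and 0.218 in epithelial cells. At an unadjusted p under 0.05 the estimated correlation gave 0 of 23 lists in both compartments, and fry gave 5 in fibroblasts and 2 in epithelial cells. In simulated data with 1 raised list of log2 0.5, camera with the preset correlation gave adjusted p = 1.15e-34 for it in the fibroblast setting and 2.04e-16 in the epithelial setting. With an estimated correlation the same lists gave adjusted p = 0.106 and 0.508, and fry gave adjusted p = 0.17 and 0.43. Both tests thus missed a list known to have changed. The simulated genes were independent of each other, close to what the preset correlation assumes. The simulation therefore cannot show whether calls with the preset correlation hold in the real libraries. Camera results with the preset correlation treat the genes of a list as nearly independent and are given as such. Counts of list members that pass over all genes stand beside counts adjusted over the list alone.

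The named genes followed a rule. It took Yap1, Wwtr1 and Wnt4, then the 10 largest rises and the 10 largest falls among changed genes whose knockdown libraries both lay on the same side of both controls at a mean of at least 10 CPM, without predicted genes and pseudogenes. It also took up to 4 members of each pathway list by smallest p; some of these are not reported here. In AT2 and AT1 cells, and for each direction of the difference between compartments, 5 were taken. The design, classes of test, lists, markers, naming rule and most alternatives were fixed before the data were examined. The mixed and AT1-like assignments, the setting apart of cluster 32, the share of cycling fibroblasts, and the corrections for gene length, GC content and free RNA were chosen after seeing the data.

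Shares of cells are given per library with 95% exact binomial (Clopper-Pearson) intervals, which cover counting error only. Group shares were compared by two-sided exact permutation tests, which with 2 libraries against 2 cannot give a p below 0.333. For shares of cells with a UMI of Mki67 or Top2a, every cell was thinned to 2000 UMIs and shallower cells were left out. Scrublet in scanpy 1.11.5 called 4, 1, 715 and 119 doublets in control 1, control 2, knockdown 1 and knockdown 2; at 0.027% and 0.007% of the control cells it has not worked there, so doublets were removed only through the mixed clusters, and the highest 6% of scores per library were left out as an alternative. Droplets also hold free RNA from other cells. Fibroblast markers in epithelial cells stood at 12.1%, 8.57%, 8.53% and 5.93% of their fibroblast level in the 4 libraries, and AT2 markers in fibroblasts at 1.17%, 0.873%, 2.15% and 1.06% of their AT2 level.

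Coordinates are from GENCODE vM21 (GRCm38), in which 32158 of the 32285 gene IDs were found. The pipeline was tested on counts simulated from the real means with 200 genes changed. In the fibroblast setting edgeR recovered 71 of 100 genes changed by log2 1 and 96 of 100 changed by log2 2, with 20 false calls over 17239 genes tested. In the epithelial setting it recovered 57 and 96 of 100, with 5 false calls over 13739 genes. For the difference between compartments it recovered 30 of 74 and 70 of 73, with 8 false calls over 13715 genes. Among the genes called, the false share was above the adjusted p threshold in the fibroblast setting and for the difference between compartments. In the epithelial setting it was below that threshold. The real fibroblast and between-compartment calls may therefore hold more false calls than the threshold implies. Whether trends on gene length between the real libraries add false calls was not tested. The alternatives were DESeq2, limma voom, RLE scaling, no filter on low counts, thinned sums, deeper cells only, other doublet and cluster choices, each library left out in turn, and the replicate number as a block.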

Results

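Single-cell RNA profiles were collected from 2 control and 2 fibroblast YAP/TAZ knockdown alveolosphere cultures. Control libraries 1 and 2 held 15000 and 13883 cells with 71523447 and 70525226 UMIs. Knockdown libraries 1 and 2 held 10545 and 6508 cells with 63758826 and 44284602 UMIs. Median depth per cell was 3875.5 and 4142 UMIs in the controls and 4961 and 5946 UMIs in the knockdowns, so UMI counts per cell were higher in the knockdowns. The median mitochondrial share was 23.4%, 21.5%, 24.6% and 17.8% in the same order. Fibroblast classes held 12041, 11480, 7472 and 5123 cells, and epithelial classes held 2233, 1749, 2589 and 1274 cells. The series title names Wnt4 as a signal between the compartments, so the comparisons address what the knockdown changed in the fibroblasts, what changed in the epithelium grown with them, and whether the responses differed.

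The targeted genes were examined first. Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596, minus strand) encodes YAP, the co-activator restrained by Hippo kinase signalling. Its fibroblast level was 61.3 and 64.9 CPM in the controls and 40.9 and 36.4 CPM in the knockdowns, a log2 fold change of -0.71 ± 0.11 (SE) with adjusted p = 0.00864. Without knockdown library 2 the change was -0.62 with adjusted p = 0.0559, the highest of a range from 3.98e-05 to 0.0559 over the 18 alternatives. Wwtr1 (ENSMUSG00000027803, chromosome 3, 57455649 to 57575910, minus strand), which encodes TAZ, read 239 and 231 CPM in the controls and 194 and 171 CPM in the knockdowns. Its log2 fold change of -0.36 ± 0.13 did not pass (adjusted p = 0.115), nor did it under 17 of the 18 alternatives. Which part of the transcripts the knockdown targets is not given in the sources used here, so the 3' counts of both genes may include transcript that it leaves in place. In epithelial cells Yap1 went from 104 ± 9.59 to 92.4 ± 0.723 CPM (SD, n = 2 libraries per group) and Wwtr1 from 292 ± 29.7 to 226 ± 24.7 CPM, with adjusted p = 0.697 and 0.486. The fibroblast effect on Yap1 exceeded the epithelial effect by -0.57 ± 0.13 (adjusted p = 0.0316), which was lost under 6 of 19 alternatives, among them DESeq2 and leaving out control library 2 or knockdown library 1 (adjusted p from 5.97e-05 to 0.278). The effects on Wwtr1 differed by -0.03 ± 0.11 (adjusted p = 0.927).

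In the fibroblasts, Wnt ligands and modulators rose as a list with the knockdown, beside large single rises of Mmp9, Adgrg1 and Angpt2. Cell cycle genes, known YAP/TAZ targets and contractile genes fell as lists, and the collagen genes Col8a1 and Col11a1 were among the largest falls. With an estimated correlation these lists were not called (adjusted p = 0.675, and 0.787 for contractile genes), and the contractile list was also not called without control library 2 or knockdown library 1. Wnt4 (ENSMUSG00000036856, chromosome 4, 137277489 to 137299726, plus strand), a secreted Wnt ligand, rose from 31.9 ± 0.0743 to 83.5 ± 11.9 CPM, a log2 fold change of 1.39 ± 0.13 with adjusted p = 0.00146. It was called under all 18 alternatives, with log2 fold changes from 1.23 to 1.56. Of 17481 genes tested, 773 rose and 1087 fell; 655 of these 1860 changed by at least 2-fold, and 4975 had an unadjusted p under 0.05. The count was 998 without knockdown library 2, 1176 without knockdown library 1 and 3666 without control library 2, where 1987 rose and 1679 fell. Long genes tended to be lower in the knockdown libraries: across 8748 genes the log2 fold change and gene length had a Spearman rho of -0.456, and the difference between the 2 controls and between the 2 knockdowns followed length as well (rho 0.434 and 0.506). Genes are not independent replicates, so these have no p-value.

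**Figure D1:**
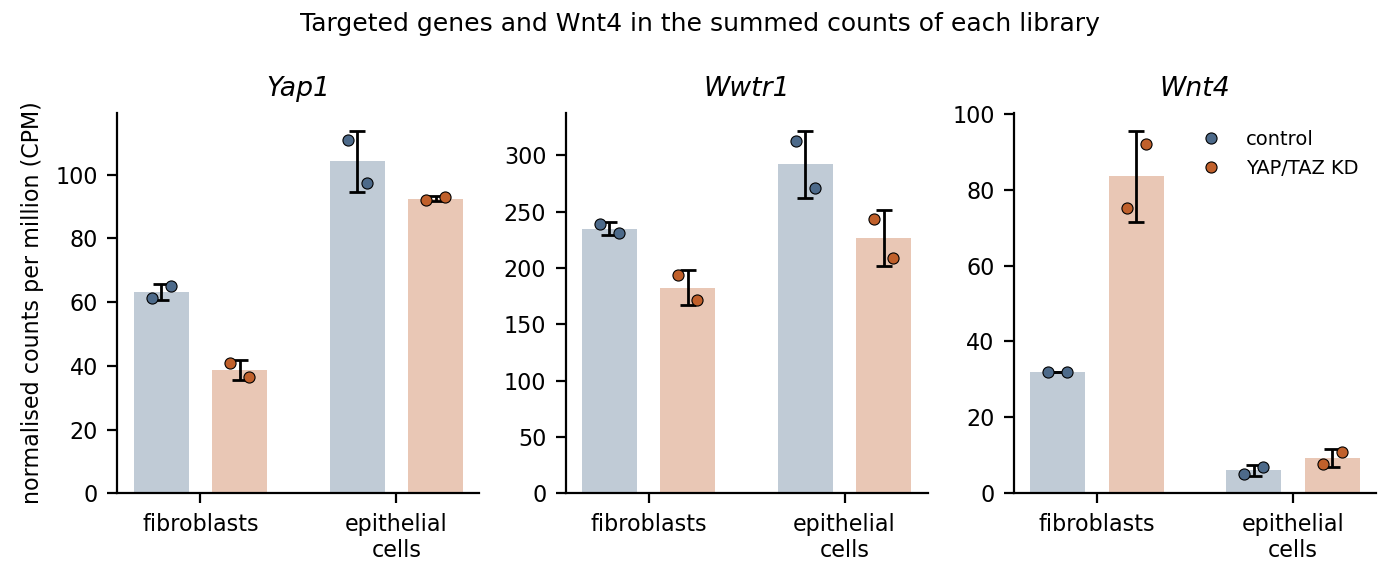
Normalised CPM of Yap1, Wwtr1 and Wnt4 in fibroblasts and epithelial cells, with 1 point per library and bars for the mean ± SD of 2 control and 2 knockdown libraries. In fibroblasts Yap1 sits at 61.3 and 64.9 CPM in controls against 40.9 and 36.4 CPM in knockdowns, and Wnt4 at 32.0 and 31.9 CPM against 75.1 and 92.0 CPM.

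Among the largest rises, the gelatinase Mmp9 went from 7.33 ± 1.85 to 239 ± 6.40 CPM (log2 5.02 ± 0.20, adjusted p = 3.29e-05). The adhesion G protein-coupled receptor Adgrg1 went from 3.94 to 101 CPM (log2 4.68 ± 0.14, adjusted p = 8.71e-06) and rose in every fibroblast class tested. Plch2, a phospholipase C, rose by log2 4.36 ± 0.16, and Angpt2, the angiopoietin that antagonises Tie2 in vessels, by log2 3.60 ± 0.26 (adjusted p = 3.29e-05 and 0.000499). Megf11 rose from 32.8 to 238 CPM, the kinase gene Dapk3 from 5.77 to 38.1 CPM, the transcription factor gene Cebpb from 70.8 ± 15.3 to 442 ± 229 CPM and Etl4 from 23.7 to 130 CPM, with adjusted p of 6.61e-05, 6.61e-05, 0.00456 and 6.15e-05. Cldn2, a tight junction claudin, rose by log2 2.57 ± 0.19 (adjusted p = 0.00068). Pcp4, a calmodulin-binding peptide gene, read 0.0362 CPM in controls and 40.0 ± 3.33 CPM in knockdowns (adjusted p = 1.97e-06). Its level in the knockdown cells of the small epithelial cluster 32 was 8707 CPM. In fibroblast classes without a control count, its knockdown level lay between 27.3 CPM (cycling) and 53.3 CPM (Wnt4-positive). Free epithelial RNA, taken at the level of AT2 markers in fibroblast droplets, would give 0.243 of its fibroblast knockdown level.

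Among the largest falls, the collagens Col8a1 and Col11a1 went from 88.1 ± 16.5 to 19.7 ± 4.36 CPM and from 26.4 to 6.42 CPM (log2 -2.16 ± 0.19 and -2.04 ± 0.13, adjusted p = 0.00117 and 0.000384). Hs6st2, a heparan sulfate sulfotransferase, fell by 2.29 on the log2 scale, Clca3a1 by 2.64, Brinp3 by 2.28 and the neutrophil collagenase Mmp8 by 1.78 (adjusted p = 6.61e-05, 6.61e-05, 0.00185 and 0.00403). The others of the 10 were Ltf (lactoferrin), Cbr2, Fxyd3 and Pglyrp1, with adjusted p of 0.00896, 0.0422, 0.00562 and 0.00767. These 4 read higher in control epithelial cells (114, 201, 36.8 and 68.7 CPM) than in control fibroblasts (33.5, 137, 18.2 and 26.6 CPM). Cbr2 did not pass with DESeq2 (adjusted p = 0.132).

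Both lists of the targeted pathway fell by camera with the preset correlation. They share Amotl2 and Lats2, and the Hippo list holds the targeted genes Yap1 and Wwtr1, so they are not separate support. Of 21 measured Hippo pathway genes, 0 rose, 4 fell and 17 did not pass, with 5 falls adjusted over the list alone (median log2 -0.18, camera adjusted p = 0.00181, adjusted p = 0.675 with an estimated correlation). They were Yap1 itself, the TEAD cofactor Vgll3 (log2 -1.40 ± 0.12), the angiomotin Amotl2 (-0.91 ± 0.12) and the scaffold gene Wwc2 (-0.64 ± 0.11, adjusted p = 0.0139). The Wwc2 call was lost without knockdown library 2 (adjusted p = 0.0955). Of 22 known YAP/TAZ targets 5 fell, 1 rose and 16 did not pass, or 8 falls and 2 rises adjusted over the list alone (median log2 -0.21, camera adjusted p = 0.00599, adjusted p = 0.675 with an estimated correlation). Crim1, a BMP-binding membrane protein gene, fell from 83.3 to 38.5 CPM, the cardiac ankyrin repeat gene Ankrd1 from 6.22 to 3.04 CPM and the tissue factor gene F3 from 93.9 to 55.3 CPM (adjusted p = 0.00148, 0.00767 and 0.00847). Amotl2 and Ptpn14 also fell, and Foxf2 rose. The listed targets Ccn1 and Ccn2 were not among the genes that passed.

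Among 22 Wnt ligands and modulators, 9 rose (Wnt4, Wnt2, Wnt5a, Wnt11, Rspo2, Dkk2, Dkk3, Sfrp4 and Wif1), Rspo3 fell and 12 did not pass, with 11 rises and 1 fall adjusted over the list alone. The median was log2 0.58 and camera gave adjusted p = 1.05e-06, with adjusted p = 0.675 with an estimated correlation. The risen genes include both ligands and secreted antagonists: Wnt11 went from 5.20 to 10.5 CPM, and the antagonist genes Dkk2 and Dkk3 from 25.9 to 54.7 CPM and from 92.2 to 196 CPM (adjusted p = 0.0049, 0.00176 and 0.00413). Of 18 Wnt/beta-catenin targets, 5 rose (Apcdd1, Dkk2, Notum, Sp5 and Wif1), 3 fell (Ccnd1, Lgr6 and Nkd2) and 10 did not pass, or 5 and 5 adjusted over the list alone, and camera did not call the list (adjusted p = 0.539). Lgr6, an R-spondin receptor, changed by log2 -1.41 ± 0.19 and Nkd2, a feedback inhibitor, by -1.60 ± 0.13. Growth factors of the AT2 niche were not called either (adjusted p = 0.14): 4 of 23 rose (Angptl4, Fst, Il33 and Tgfb3), 3 fell (Angpt1, Il6 and Lif) and 16 did not pass, or 10 rises and 3 falls adjusted over the list alone. Fst, the activin antagonist follistatin, rose from 100 to 279 ± 39.5 CPM (log2 1.48 ± 0.18, adjusted p = 0.00344), and Angpt1, the angiopoietin that activates Tie2, fell from 38.7 to 15.1 CPM (log2 -1.35 ± 0.15, adjusted p = 0.00297). The Il6 call was lost without knockdown library 1 or 2 (adjusted p = 0.0656 and 0.0582).

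**Figure D2:**
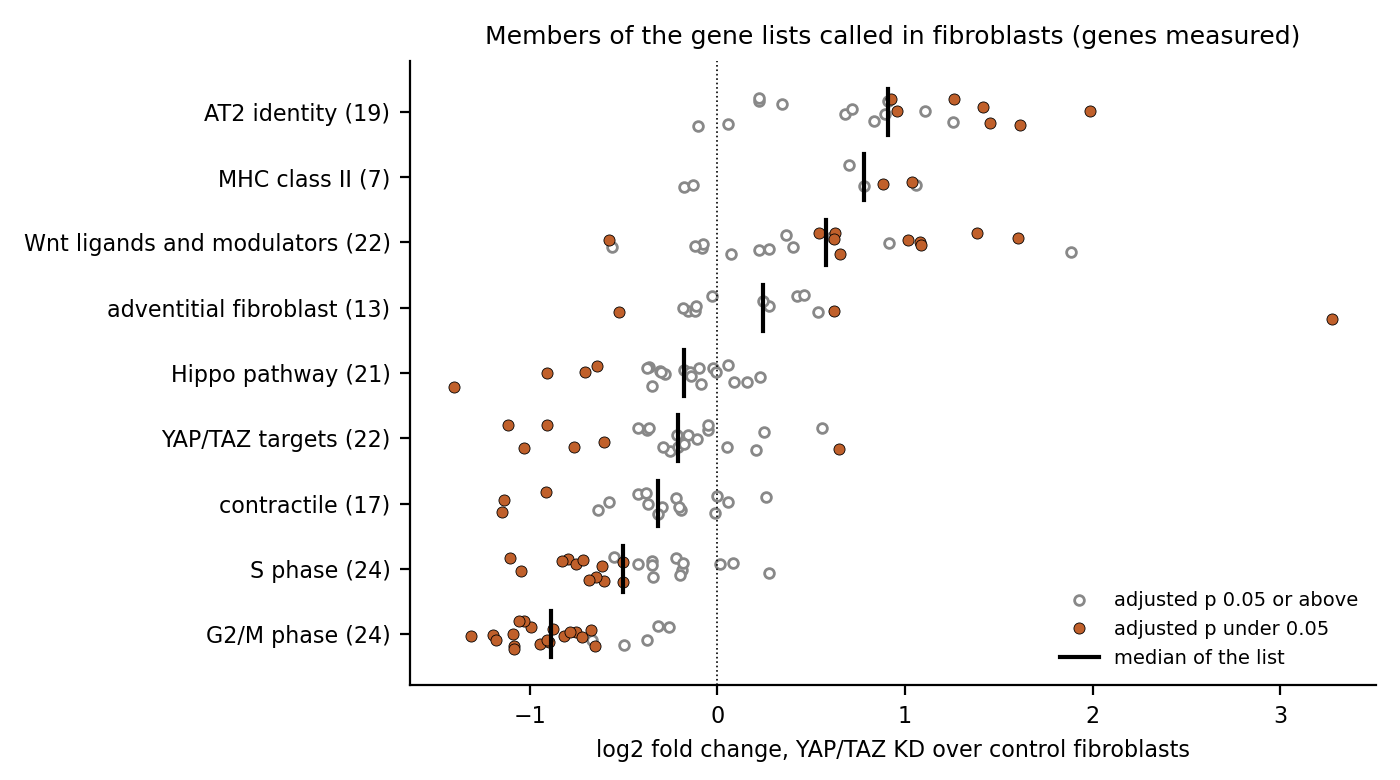
Log2 fold change (knockdown minus control) in fibroblasts of each measured member of the 9 lists that camera called with the preset correlation. Filled points have an adjusted p under 0.05 over all genes and lines mark medians; G2/M genes have a median of -0.88 and Wnt ligands and modulators one of 0.58.

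Cell cycle genes fell together in the fibroblasts. Of 24 G2/M genes 19 fell and 5 did not pass, or 21 falls adjusted over the list alone (median log2 -0.88, camera adjusted p = 5.99e-19, adjusted p = 0.675 with an estimated correlation). Mki67, which marks cycling nuclei, went from 29.9 ± 3.15 to 14.1 ± 1.04 CPM, and the kinetochore genes Ndc80 and Cenpe fell by 1.18 and 1.31 on the log2 scale (adjusted p = 0.00302, 0.00403 and 0.00445). Of 24 S phase genes 12 fell and 12 did not pass, or 14 falls adjusted over the list alone (median log2 -0.50, camera adjusted p = 2.32e-07, adjusted p = 0.675 with an estimated correlation). The replication genes Dtl and Pola1 changed by -1.04 ± 0.11 and -1.11 ± 0.12. Much of the fall went when each fibroblast class of at least 50 cells per library had the same weight in every library. The fallen G2/M genes then went from a median of log2 -0.94 to -0.22 and the fallen S phase genes from -0.70 to -0.26. After thinning to 2000 UMIs, 11.2% (95% interval 10.6 to 11.8) and 11.4% (10.8 to 12.0) of control fibroblasts carried a UMI of Mki67 or Top2a, against 4.96% (4.47 to 5.48) and 5.53% (4.92 to 6.20) of knockdown fibroblasts, a difference of -6.02 percentage points (exact permutation p = 0.333, the smallest possible). Without thinning the shares were 18.7% and 10.4%. Thinning left out fibroblasts under 2000 UMIs, keeping 93.6% in controls and 97.9% in knockdowns. Myo1f-positive fibroblasts, taken as the background class, read 4.90 ± 0.0590% and 2.62 ± 1.89% (1.28% in knockdown library 2), at median depths of 3691 and 3902 UMIs in controls and 5036 and 5898.5 UMIs in knockdowns. All fibroblasts had median depths of 3764 and 4037 UMIs in the controls.

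The contractile and matrix programmes moved less evenly. Of 17 contractile genes 3 fell (Des, Lmod1 and Synpo2) and 14 did not pass, or 4 falls adjusted over the list alone (median log2 -0.31, camera adjusted p = 0.00842, adjusted p = 0.787 with an estimated correlation); the camera call was lost without control library 2 (adjusted p = 0.0998) and without knockdown library 1 (0.0694). Lmod1 did not pass without knockdown library 1 (adjusted p = 0.0514). Desmin (Des), a muscle intermediate filament, fell from 52.6 to 23.9 CPM (adjusted p = 0.00784). Smooth muscle markers, a list that overlaps this one, had 3 of 9 members falling. Among 24 extracellular matrix genes 3 fell (Postn, Lox and Col12a1) and 21 did not pass, or 4 falls and 1 rise adjusted over the list alone, and the list was not called (adjusted p = 0.24). Periostin (Postn) went from 26.2 to 13.3 CPM (adjusted p = 0.00358); Lox and Col12a1 lost their calls without either knockdown library. Of 16 TGF-beta response genes 3 fell, among them Itga11 and Ltbp2, and 13 did not pass, or 7 falls and 2 rises adjusted over the list alone (adjusted p = 0.131). Itga11, a collagen receptor, changed by log2 -1.58 ± 0.21 (adjusted p = 0.0046).

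Markers of fibroblast subtypes shifted in both directions. Of 13 adventitial fibroblast genes, Cd34 and Ly6c1 rose, Col14a1 fell and 10 did not pass, or 5 rises and 1 fall adjusted over the list alone (median log2 0.25, camera adjusted p = 0.012, adjusted p = 0.675 with an estimated correlation; lost without control library 1, 0.171, and knockdown library 1, 0.0667). Of 19 alveolar fibroblast and lipofibroblast genes, Inmt and Wnt2 rose, Gpc3, Limch1 and Slit2 fell and 14 did not pass, or 8 rises and 3 falls adjusted over the list alone (adjusted p = 0.497). Col14a1 was lost under 5 of 18 alternatives, among them the fits without control library 2 or either knockdown library, and Ly6c1 under 2 of 17, among them the fit without knockdown library 2 (highest adjusted p = 0.211 and 0.0769). Inmt, a methyltransferase gene of alveolar fibroblasts, went from 37.0 to 68.5 CPM, and Slit2, a secreted guidance cue, from 706 to 357 CPM (adjusted p = 0.0105 and 0.00607). Inflammatory genes were not called (adjusted p = 0.24, median log2 -0.04 but mean 0.28): the chemokine genes Ccl11, Ccl20 and Cxcl5 and the cytokine gene Csf2 rose, Il6 fell and 15 did not pass, with the same 4 and 1 adjusted over the list alone. Cxcl5 lost its call under 4 of 18 alternatives, among them the fits without either knockdown library (highest adjusted p of the 4, 0.231). Free epithelial RNA, taken at the level of AT2 markers in fibroblast droplets, would give 0.701 of the knockdown level of Ccl20. Ccl11 (eotaxin) rose from 47.8 ± 20.3 to 200 ± 17.4 CPM (adjusted p = 0.00425).

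AT2 transcripts were also higher in the fibroblast droplets. Of 19 AT2 identity genes 7 rose (Cebpa, Cxcl15, Lamp3, Lyz2, Nkx2-1, Sftpa1 and Sftpb) and 12 did not pass, or 12 rises adjusted over the list alone (median log2 0.91, camera adjusted p = 5.24e-08, adjusted p = 0.675 with an estimated correlation). Lyz2 rose by log2 1.99 ± 0.22 and Sftpa1 by 1.45 ± 0.14. AT2 markers in fibroblasts stood at 1.17% and 0.873% of their AT2 level in controls and 2.15% and 1.06% in knockdowns. MHC class II genes, which AT2 cells also express, had 2 of 7 rises (Cd74 and H2-DMb1), or 4 adjusted over the list alone (camera adjusted p = 0.0186, adjusted p = 0.675 with an estimated correlation); that call was lost with a length correction and without knockdown library 1 (adjusted p = 0.0785 and 0.13). Among markers of other cell types in the fibroblast sums, 5 of 6 basal, 5 of 8 ciliated and 3 of 4 mesothelial markers fell, their summed levels going from 20.4 to 1.89, 22.4 to 11.6 and 44.6 to 14.8 CPM. Summed secretory airway markers read 826.5 CPM in control and 162 CPM in knockdown fibroblasts, with 0 of 7 passing over all genes or adjusted over the list alone. The immune markers Ptprc and Tyrobp rose.

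The remaining lists were not called in fibroblasts. Of 20 interferon response genes 2 rose (Ifit3 and Ifit3b), or 1 adjusted over the list alone (adjusted p = 0.732, median log2 -0.01 but mean 0.08). Of 15 hypoxia and glycolysis genes Vegfa rose and Pfkp and Egln3 fell, or 2 rises and 3 falls adjusted over the list alone (adjusted p = 0.648). Of 15 p53 and senescence genes Igfbp7 and Cdkn2b rose, the same count adjusted over the list alone (adjusted p = 0.14); Igfbp7, a secreted IGF-binding protein gene, went from 901 ± 320 to 2572 ± 13.5 CPM. Of 16 immediate early and heat shock genes Zfp36 rose, with 0 calls by edgeR adjusted over the list alone, 4 at an unadjusted p under 0.05 and 1 call each by DESeq2 and limma voom (adjusted p = 0.0745). Of 20 AT1 genes 3 rose and Cav1, the caveolin gene, fell from 10.0 to 2.07 CPM, or 4 rises and 3 falls adjusted over the list alone (adjusted p = 0.61). Of 18 transitional epithelium genes Plaur rose and Krt19 and Lgals3 fell, or 3 rises and 2 falls adjusted over the list alone (adjusted p = 0.873, with a downward test but a median of log2 0.03 and a mean of 0.01). Surfactant lipid and cholesterol genes (Fabp5 and 1 other of 20 passed, in opposite directions) and Notch genes (Notch3 up, Dlk1 down of 13) had the same counts adjusted over the list alone (adjusted p = 0.755 for both). The calls of Ifit3b, Zfp36, Plaur and Dlk1 were each lost under at least 5 alternatives. Without 1 of the knockdown libraries, Cdkn2b, Vegfa, Pfkp, Egln3, Fabp5 and Notch3 also did not pass (highest adjusted p = 0.175, 0.0514, 0.0547, 0.115, 0.0722 and 0.107), nor did Cdkn2b without control library 1.

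The fibroblast classes differed in size between the groups. Wnt4-positive fibroblasts numbered 7 and 32 cells in controls and 1362 and 971 in knockdowns, Tgfbi-positive fibroblasts 5, 38, 931 and 404, and smooth muscle cells 724, 753, 48 and 5 in the same order. Clusters built on expression follow such transcripts, so these sizes are not compared as shares. Wnt4 itself also rose inside classes present in both groups. Plain CPM went from 85.9 to 206 in inflammatory fibroblasts 2, from 15.1 to 47.3 in myofibroblast-like cells, from 32.1 to 62.3 in the class deposited as fibroblasts and from 13.3 to 28.8 in cycling fibroblasts (adjusted p = 0.000163, 4.9e-05, 0.00101 and 0.00597). It also rose in EMT-like cells and inflammatory fibroblasts 1 (adjusted p = 0.0195 and 0.0173), and did not pass in unknown mesenchymal cells or Myo1f-positive fibroblasts (adjusted p = 0.308 and 0.523). A class can span several clusters, as the class deposited as fibroblasts holds clusters 0, 5, 8, 11 and 18. Control and knockdown cells of a class may therefore lie in different clusters, which was not examined. Yap1 fell in EMT-like cells, the class deposited as fibroblasts and myofibroblast-like cells (adjusted p = 0.0148, 0.00634 and 0.0226). In the tested classes 115 to 1199 genes changed, the fewest in unknown mesenchymal cells.

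In the epithelium summed over its classes, the knockdown fibroblasts went with higher cell cycle and AT2 transcripts as lists and lower matrix transcripts. Unlike the fibroblast classes, the epithelial classes were not given the same weight in every library. Cycling AT2 cells were 238 of 2233 and 205 of 1749 epithelial cells in controls, and 472 of 2589 and 164 of 1274 in knockdowns. Within transitional cells the G2/M list was lower. Class shares may therefore account for part of the cell cycle and AT2 rises, which was not tested. Fibroblast markers in the epithelial sums had a median of log2 -0.59, and the matrix list shares genes such as Col1a2 and Col3a1 with them. Free fibroblast RNA may therefore account for part or all of the matrix fall. AT2 transcripts rose in fibroblast droplets too, and free AT2 RNA was not weighed within the epithelium. The list calls were lost with an estimated correlation (adjusted p = 0.881), and 0 of 24 S phase, 1 of 24 G2/M and 0 of 19 AT2 genes passed edgeR's test; 8 S phase and 7 AT2 genes had an unadjusted p under 0.05, and DESeq2 and limma voom called 0 of either list. Of 13952 genes tested, 95 rose and 106 fell, and 1586 had an unadjusted p under 0.05. Of these 201 genes 162 changed by at least 2-fold. The count was 129 without cluster 32, a small cluster whose control and knockdown cells differed in kind, and it was 373 without control library 2, 684 without knockdown library 1 and 416 without knockdown library 2. The trend on gene length had a rho of -0.572 across 9185 genes. Wnt4 read 6.05 ± 1.40 and 9.29 ± 2.33 CPM (adjusted p = 0.393), and free fibroblast RNA was not weighed for these levels.

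Of the largest rises, C2cd4b (chromosome 9, 67759437 to 67760930, plus strand), a nuclear calcium-dependent domain protein gene, went from 3.34 to 28.1 CPM (log2 3.06 ± 0.21, adjusted p = 3.39e-06). In AT2 cells alone it went from 9.41 to 55.6 CPM. Dapk3 (log2 2.84 ± 0.20, adjusted p = 4.58e-06), Cebpb (2.60 ± 0.30, 0.000349) and Mmp9 (2.94 ± 0.27, 3.84e-05) were higher in the epithelium as well as in the fibroblasts. Free fibroblast RNA, taken at the level of fibroblast markers in epithelial droplets, would give 0.0547, 0.221 and 0.726 of their knockdown level. Dapk3 and Cebpb rose in every class tested; whether the groups shared mouse strain, transgenes and AT2 donors is not given in the sources used here. Kcnk3, Pcp4, Tafa2, Ccl20, Oit1 and Cdh2 completed the 10 largest rises, with adjusted p from 5.62e-08 to 0.00173, and in the knockdown epithelium were highest in cluster 32, which they help to define. That cluster held 82, 25, 21 and 42 cells, too few to test. When all cells were clustered anew, 82.2% of its control cells joined a cluster led by airway secretory genes, which took 14.3% of its knockdown cells. Of its knockdown cells 77.8% joined a cluster led by Pcp4 and Ccl20 with the AT1 genes Clic5 and Ager, which took 3.7% of its control cells. Levels in cluster 32 therefore largely compare different kinds of cells. Its knockdown cells read Pcp4 at 8707 CPM, Ccl20, a chemokine gene, at 1398 CPM and Cdh2 (N-cadherin) at 616 CPM. Without it Pcp4 and Tafa2 still passed (log2 5.47 and 2.53, adjusted p = 0.0448 for Tafa2), Ccl20 had log2 1.00 (adjusted p = 0.431), Oit1 -0.03 and Cdh2 -0.29, and Kcnk3 had too few counts to be tested.

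Among the falls, Adam28, a metalloproteinase gene, went from 62.8 to 4.66 CPM (log2 -3.79 ± 0.31, adjusted p = 1.15e-05), Ifitm1 from 59.1 to 8.65 CPM (-2.79 ± 0.22, 9.29e-06) and the carbonyl reductase gene Cbr2 from 198 to 18.5 CPM (-3.48 ± 0.50, 0.00173). Ltf read 112 ± 86.0 and 8.61 CPM, with adjusted p = 0.0433 and a call lost under 8 alternatives. Adam28, Cbr2 and Ltf read 1059, 1858 and 1622 CPM in the control cells of cluster 32. The water channel gene Aqp4, Slit3, Ptn, Abi3bp, Galnt18, Plcb1 and Igfbp3 also fell. DESeq2 did not call Aqp4, Cbr2, Slit3 or Abi3bp (adjusted p = 0.291, 0.106, 0.348 and 0.42), and Galnt18 and Plcb1 did not pass without cluster 32 (0.0925 and 0.256). Ptn and Igfbp3 each lost their call under 4 of 18 alternatives (highest adjusted p = 0.141 and 0.184). Free fibroblast RNA, taken at the level of fibroblast markers in epithelial droplets, would give 3.71 times the control level of Slit3, 1.75 times that of Abi3bp and 0.992 of that of Plcb1.

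**Figure D3:**
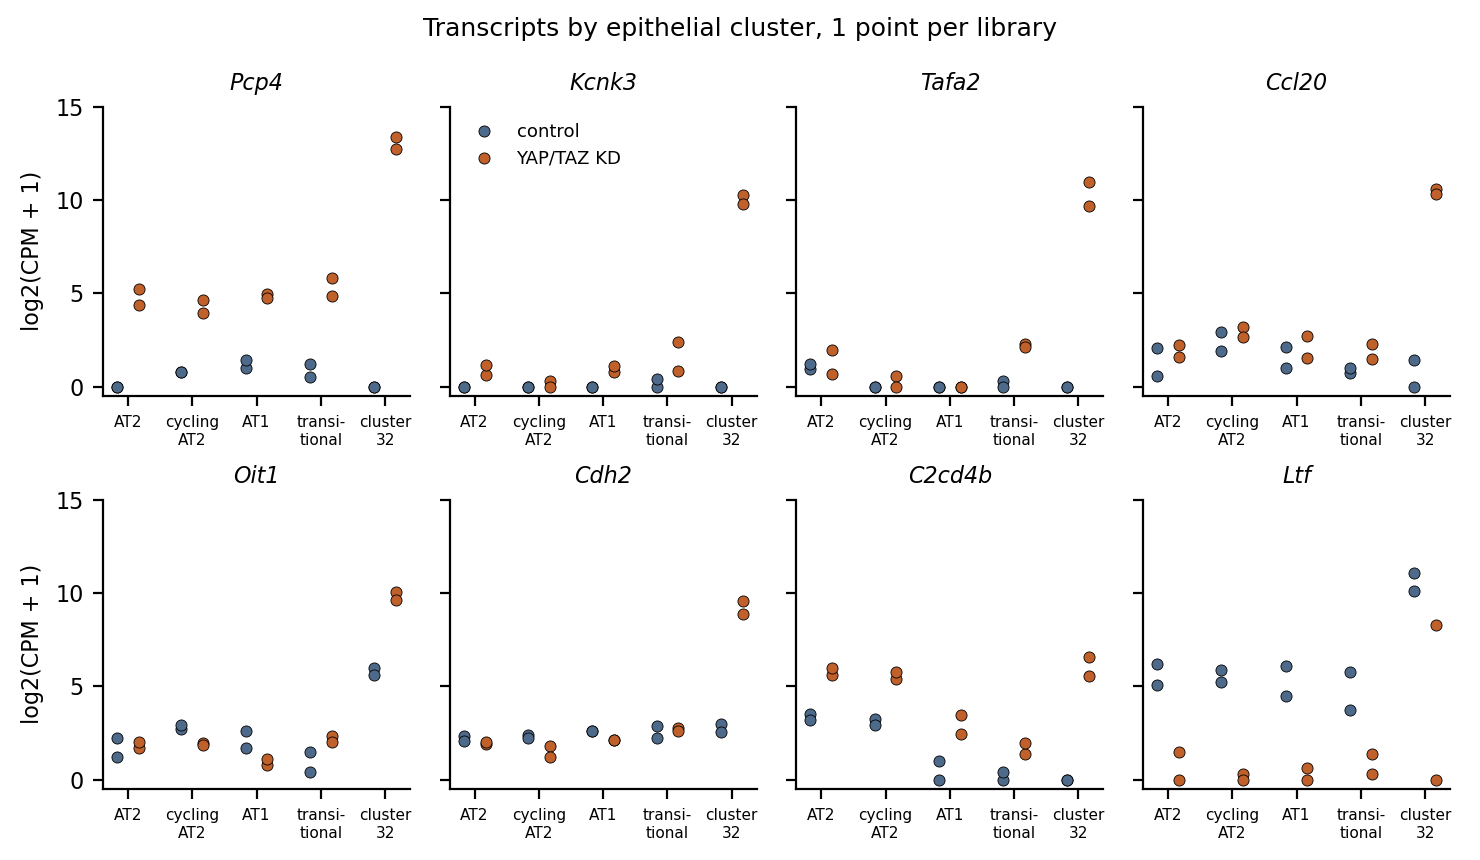
Log2(CPM + 1) of 8 genes in each epithelial cluster, with 1 point per library, for 2 control and 2 knockdown libraries. Pcp4 reaches 8707 CPM on average in the cells of cluster 32 in the knockdown libraries and 28.4 CPM in AT2 cells, while C2cd4b in knockdowns is higher in cluster 32, AT2 and cycling AT2 cells than in AT1-like and transitional cells.

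Extracellular matrix genes fell as a list in the epithelium: 4 of 24 fell (Col1a2, Col12a1, Postn and Timp1) and 20 did not pass, or 6 falls adjusted over the list alone (median log2 -0.38, camera adjusted p = 1.31e-09, adjusted p = 0.881 with an estimated correlation). Timp1, a metalloproteinase inhibitor gene, went from 286 ± 7.12 to 127 ± 2.93 CPM (adjusted p = 0.00273). The Col1a2 and Col12a1 calls were lost without control library 1 or knockdown library 2, and Col12a1 also without cluster 32. Free fibroblast RNA would give 1.05, 0.554, 0.531 and 0.672 of the control level of Col1a2, Col12a1, Postn and Timp1. Of 15 fibroblast markers in the epithelial sums 1 fell, Col1a2, or 6 adjusted over the list alone (median log2 -0.59), and their sum was 3333 CPM in controls and 2631 CPM in knockdowns. Contractile genes were called downward (1 of 15 fell, Des, also 1 adjusted over the list alone; median log2 -0.10, adjusted p = 0.0276, and 0.881 as adjusted p with an estimated correlation), but not without control library 2 or knockdown library 1. Basal cell markers fell in 4 of 5 cases, from 38.4 to 7.01 CPM summed.

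Cell cycle lists were called upward in the epithelium summed over its classes, without equal class weights. The difference from the fibroblasts was not tested for lists. G2/M genes had a median of log2 0.44, with 1 of 24 rising (Nuf2, from 7.49 to 14.9 CPM, adjusted p = 0.0383) and 23 not passing, or 7 rises adjusted over the list alone (camera adjusted p = 4.86e-09, adjusted p = 0.881 with an estimated correlation). The Nuf2 call was lost under 9 of 19 alternatives, among them the fits without control library 1 (adjusted p = 0.141, the highest) or knockdown library 1 (0.0561), DESeq2 (0.0828) and limma voom. Of 24 S phase genes 0 passed edgeR's test over all genes or adjusted over the list alone, where 8 had an unadjusted p under 0.05 and DESeq2 and limma voom also called 0. Their median was log2 0.31 (camera adjusted p = 8.31e-05, adjusted p = 0.881 with an estimated correlation); Mcm5 and Mcm2 had log2 fold changes of 0.54 and 0.61. The share of epithelial cells with a UMI of Mki67 or Top2a after thinning was 12.4% (256 of 2069 cells, upper bound 13.9) and 11.3% (9.79 to 12.9) in controls and 14.6% (13.3 to 16.0) and 12.6% (10.8 to 14.5) in knockdowns; the intervals of control library 2 and knockdown library 1 did not overlap, and those of the other pairs of a control and a knockdown library did. The difference was 1.76 percentage points (exact permutation p = 0.333), at unthinned shares of 19.2% and 23.5% and median depths of 3787, 4089, 5328 and 6072.5 UMIs. Within classes the share was 6.71 ± 2.75% and 8.42 ± 1.41% in AT2 cells (exact permutation p = 0.667, with a difference of -0.225 points without control library 2), 4.53 ± 1.98% and 4.27 ± 0.809% in AT1-like cells (1) and 3.53 ± 0.330% and 1.69 ± 0.449% in transitional cells (0.333). In the deposited cycling AT2 class, which such genes define, it was 64.0 ± 1.76% and 65.1 ± 8.98% (exact permutation p = 1), and that class held 238, 205, 472 and 164 cells, the most in knockdown library 1. Thinning kept 93.5% of control and 98.6% of knockdown epithelial cells. The background class, Myo1f-positive fibroblasts, read 4.90% and 2.62%, above the transitional cells; in knockdown library 2 alone it read 1.28% against 1.37% in transitional cells.

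**Figure D4:**
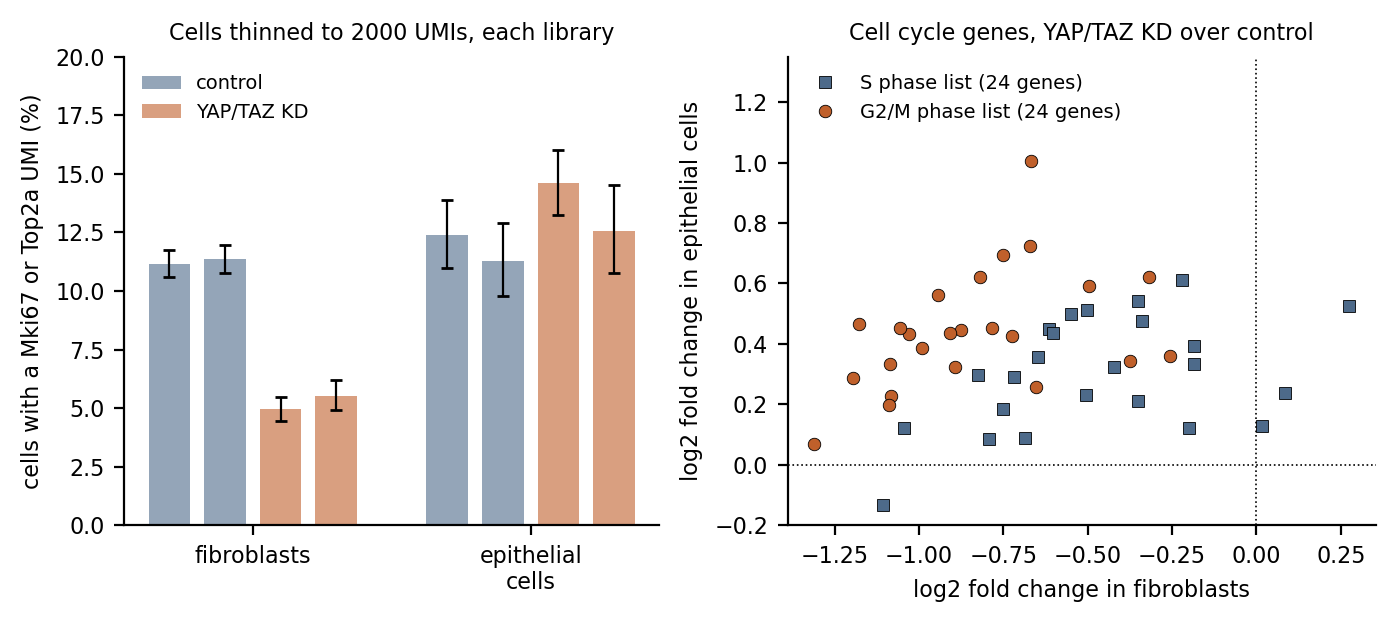
Left, percent of cells with a UMI of Mki67 or Top2a after thinning to 2000 UMIs, 1 bar per library with its 95% exact binomial interval, for fibroblasts and epithelial cells. Right, log2 fold change in fibroblasts (x) against epithelial cells (y) of 24 S phase and 24 G2/M genes; G2/M medians are -0.88 in fibroblasts and 0.44 in epithelial cells.

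AT2 identity genes rose as a list in the epithelium, although 0 of 19 passed over all genes with edgeR, DESeq2 or limma voom. With edgeR 7 had an unadjusted p under 0.05 and 2 passed adjusted over the list alone (median log2 0.41, camera adjusted p = 1.10e-05, adjusted p = 0.881 with an estimated correlation; lost without knockdown library 1, 0.136). The surfactant protein gene Sftpa1 had log2 1.04 (adjusted p = 0.15) and the transcription factor gene Cebpa 0.78 (0.0665). The list also rose within AT2, AT1 and transitional cells, with medians of log2 0.19, 0.40 and 0.64 (camera adjusted p = 0.00825, 1.31e-09 and 1.80e-12; adjusted p = 0.747, 0.872 and 0.341 with an estimated correlation), with 1, 3 and 2 of 19 members passing. In fibroblast droplets 7 of the 19 AT2 genes rose as well. Relative to their AT2 level, AT2 markers there stood at 2.15% and 1.06% in knockdowns and 1.17% and 0.873% in controls. Free AT2 RNA was not weighed for the rises in AT1-like and transitional cells. Surfactant lipid and cholesterol genes were called upward with a median of log2 0.24 and 0 of 20 passing either adjustment in edgeR, or DESeq2 and limma voom, and 2 at an unadjusted p under 0.05 (adjusted p = 0.0357, and adjusted p = 0.896 with an estimated correlation), a call lost under 3 of 10 alternatives, among them the fits without control library 1 (0.28) and knockdown library 1 (0.902). Hypoxia and glycolysis genes were called downward, with Adm (lost without control library 1 or cluster 32) and Egln3 the 2 of 15 that fell and 1 rise and 2 falls adjusted over the list alone (median log2 -0.07, adjusted p = 0.0436, and adjusted p = 0.881 with an estimated correlation); 5 of 10 alternatives lost it. Egln3, an oxygen-sensing prolyl hydroxylase gene, changed by log2 -2.50 ± 0.29 from 8.33 CPM (adjusted p = 0.000453).

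The other 16 lists were not called in the epithelium, with adjusted p from 0.0718 to 0.77. YAP/TAZ targets (Igfbp3 fell, adjusted p = 0.0917) and transitional genes (Plaur rose, 0.607; lost without control library 1, 0.154) were among them. The Hippo, Wnt/beta-catenin target, AT1, p53, interferon, immediate early, MHC class II, alveolar fibroblast and adventitial lists had 0 members past edgeR's test. At an unadjusted p under 0.05 these lists had 1, 4, 4, 1, 0, 2, 0, 3 and 3 members, and DESeq2 and limma voom called 1 alveolar fibroblast gene and 0 of the others. Among members that passed in the rest, Fst and Hes1, the Notch effector, rose, as did Ccl11 and Ccl20 among inflammatory genes, and of the Wnt modulators Rspo3 fell. Free fibroblast RNA would give 0.852 of the knockdown level of Fst and 0.916 of that of Ccl11, and 1.14 times the control level of Rspo3. Ccl20 was lost without cluster 32, Ccl11 with the mixed clusters and Rspo3 under 6 alternatives, among them the fit without control library 1 (highest adjusted p = 0.363). Dkk1, a secreted Wnt antagonist, read 0 CPM in controls and 2.89 ± 2.52 CPM in knockdowns (adjusted p = 0.0182; DESeq2, 0.094; after a length correction, 0.0633). It read 82.6 CPM in the knockdown cells of cluster 32, and without that cluster had too few counts to be tested. Hes1 was lost under 12 alternatives and Fst under 3 of 18, among them the fit without control library 2 (adjusted p = 0.066; highest of the 3, 0.301).

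AT2 cells proper (488, 492, 892 and 227 cells) had 99 changed genes of 10737 tested, 48 higher and 51 lower, with 869 at an unadjusted p under 0.05. DESeq2 called 27, of which 16 were higher, and edgeR called 40 without control library 1, 59 without control library 2 and 391 without knockdown library 1. Cebpb (18.1 to 125 CPM, adjusted p = 3.23e-11), C2cd4b (log2 2.52 ± 0.25, 3.38e-10), Dapk3 (2.65 ± 0.29, 5.41e-09) and Mmp9 (2.71 ± 0.39, 5.71e-06) rose, and Pcp4 read 0 and 28.7 CPM. The airway secretory genes Ltf, Bpifa1, Scgb3a1 and Reg3g fell along with Cbr2, and of these DESeq2 did not call Ltf, Bpifa1, Scgb3a1 or Reg3g, nor did edgeR with the mixed clusters. Summed secretory airway markers also read lower in the whole knockdown epithelium (851 and 305 CPM) and in knockdown fibroblasts (826.5 and 162 CPM). Of these markers 1 of 8 fell in the epithelium (Muc16), or 4 adjusted over the list alone. In fibroblasts 0 of 7 passed by either adjustment. AT1-like cells (393, 366, 437 and 249 cells) had 54 changed genes of 10584, with 28 higher and 26 lower and 962 at an unadjusted p under 0.05; the count was 15 without control library 1, 140 without control library 2 and 133 without knockdown library 1. Pcp4, Mmp9, Dapk3, Cebpb and the lysozyme gene Lyz2 rose, and Ltf, Bpifa1, Cbr2, Reg3g and Adam28 fell; Lyz2, Reg3g and Adam28 did not pass without control library 1 (adjusted p = 0.699, 0.466 and 0.379). Lyz2 was lost under 5 of 17 alternatives, and DESeq2 did not call Lyz2, Reg3g, Bpifa1 or Cbr2 (adjusted p = 0.125 for Cbr2 and 1 for the others). The AT2 and AT1 calls shared 21 higher genes of 45 and 28 among 10223 genes tested in both, against 0.123 for independent lists, and 16 lower genes of 42 and 25, against 0.103. The classes come from the same 4 libraries, so part of this excess may come from the shared libraries. Yap1, Wwtr1 and Wnt4 did not pass in either class (adjusted p from 0.397 to 0.954).

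No difference in cell type shares could pass the exact permutation test, whose smallest p with 2 libraries per group is 0.333. Fibroblasts made up 80.3% (79.6 to 80.9) and 82.7% (82.1 to 83.3) of control cells and 70.9% (70.0 to 71.7) and 78.7% (77.7 to 79.7) of knockdown cells, and the group means of 81.5 ± 1.71% and 74.8 ± 5.56% gave an exact permutation p of 0.333. AT2 cells, cycling AT2 cells included, were 36.2 ± 5.19% and 41.7 ± 15.6% of epithelial cells (exact permutation p = 1), with 52.7% (50.7 to 54.6) in knockdown library 1 and an interval of 28.2 to 33.3% in knockdown library 2. AT1-like cells were 19.3 ± 2.35% and 18.2 ± 1.89% (exact permutation p = 0.667), and transitional cells 42.0 ± 5.96% and 38.0 ± 11.9%. Mixed clusters held 4.47%, 4.39%, 4.33% and 1.48% of the cells. How many cells of each kind were seeded and loaded can set these shares.

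The responses of the compartments were compared directly. The knockdown effect differed between fibroblasts and epithelial cells for 610 of 17188 genes, with 184 higher in the fibroblasts and 426 lower, and 2660 at an unadjusted p under 0.05. DESeq2 called 259, and edgeR 249 without control library 1 and 975 without knockdown library 2. Without knockdown library 1 the split was 239 higher and 169 lower, and with the mixed clusters 498 and 512. Adgrg1 (fibroblast log2 4.68, epithelial 0.04) and Etl4 (2.46 and -0.28) rose in the fibroblasts and not in the epithelium, with differences of 4.61 ± 0.17 and 2.70 ± 0.14 (adjusted p = 2.59e-07 and 2.85e-06). Mmp9 was higher in both, by 2.07 ± 0.26 more in the fibroblasts (adjusted p = 0.00204, and at most 0.0507 over the alternatives, with the mixed clusters). Free fibroblast RNA would give 0.726 of its knockdown level in the epithelium. A rise of Mmp9 in epithelial cells themselves is therefore not shown, and free RNA may alter the size of the difference. Scgb1a1, the club cell secretoglobin gene, differed by -3.68 ± 0.15, and the peripheral myelin protein gene Pmp22 by -2.69 ± 0.14 (adjusted p = 3.18e-07 and 2.59e-06). Scgb1a1 read 53.9 and 4205 CPM in the cells of cluster 32 in knockdown libraries 1 and 2. Without that cluster these differences became -0.82 and -0.51 (adjusted p = 0.522 and 0.458). The Wnt4 effects differed by 0.73 ± 0.21 (adjusted p = 0.0871), so a larger response of Wnt4 in fibroblasts than in epithelium was not established by this test. Mean Wnt4 over the 4 libraries was 61.2 CPM in fibroblasts and 7.18 CPM in epithelial cells. Free fibroblast RNA was not weighed for Wnt4, and it could enter the epithelial change and shrink this difference. The difference passed under 5 of 19 alternatives, among them the fits without knockdown library 2 and with the mixed clusters (log2 from 0.48 to 1.12 and adjusted p from 0.0107 to 0.538 over all 19). Of 13715 genes tested in both compartments, 64 were higher in both, from 633 and 91 called in each, against 4.2 for independent lists, and 64 were lower in both, from 896 and 105, against 6.86; the compartments share their libraries.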

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

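The tests of gene length and GC content as the whole of a change, of the ratio between compartments, and of free RNA as a large part of a control or knockdown level were chosen after the results were seen, as were the fits without cluster 32 and with length or GC corrections.

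The knockdown effect differed between fibroblasts and epithelial cells for 610 genes by the interaction test. Adgrg1 differed by 4.61 (log2, fibroblast minus epithelial effect), Etl4 by 2.70, Mmp9 by 2.07, Moxd1 by 1.96 and Sobp by 1.96. Sobp fell in both, by -0.61 in fibroblasts and -2.53 in epithelial cells, and the difference was 1.44 without control library 1 and 1.15 without knockdown library 1, where it did not pass edgeR's test (adjusted p = 0.175 and 0.227). On the other side stood Scgb1a1 (-3.68), Pmp22 (-2.69), Apba1 (-2.56), Cdh2 (-2.39) and Fgfbp1 (-2.11). Without cluster 32, whose control and knockdown cells mostly parted when clustered anew, Scgb1a1, Pmp22, Apba1 and Cdh2 differed by -0.82, -0.51, -0.071 and 0.028, and did not pass (adjusted p = 0.522, 0.458, 0.972 and 0.982). Fgfbp1 differed by -1.36 without control library 1 and did not pass (adjusted p = 0.069).

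A measure outside the RNA comparisons also separated the libraries. The median number of ATAC fragments per cell was 13832 and 23111 in knockdown libraries 1 and 2, against 8650 and 10040 in control libraries 1 and 2. The knockdown libraries also held fewer cells with ATAC data, 10195 and 6440 against 14553 and 13439. Sequencing depth per cell was therefore not told apart from the knockdown here. The chromatin data entered no comparison.

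Transcripts of each compartment moved in the droplets of the other. AT2 transcripts were higher in knockdown fibroblasts, and their ratio to the AT2 level had an interquartile range of log2 0.612 over 13 markers at a median of 1.53%, a narrow spread that is consistent with free RNA from AT2 cells; Etv5 (log2 ratio -1.36) and Lyz2 (-4.43) stand apart from the other markers, such as Sftpb (-6.32) and do not share their ratio. Of 106 genes lower in the knockdown epithelium, 35 (33%, exact 95% interval 24.2 to 42.8) could have drawn at least 0.5 of their control level from free fibroblast RNA. That count argues against free fibroblast RNA as that much of the level for most of these genes, as far as the fibroblast markers give its amount. Its interval treats the genes as independent, which they are not. Free RNA from other cells was not tested. Summed secretory airway markers, for example, read 851 CPM in control epithelial cells and 826.5 CPM in control fibroblasts. Of the same 106, 15 (14.2%, interval 8.14 to 22.3) were at least 10 times higher in control fibroblasts, and that interval reaches past the bound of 20% below which such a source would be excluded, so a smaller part from free RNA and a response of the epithelium cannot be told apart for these genes. A response of epithelial cells to the knockdown fibroblasts, the explanation the design names, was not separately tested.

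The 64 genes higher in both knockdown compartments, with Dapk3, Cebpb and Mmp9 among them, were weighed against shared technical sources: after a length correction they kept a median share of 0.911 of their log2 fold change (interquartile 0.817 to 0.965), and after a GC correction 0.971 (0.885 to 1.00), which argues against either trend as the whole of the change. After these corrections 75% (48 of 64, exact 95% interval 62.6 to 85.0) and 81.2% (52 of 64, 69.5 to 89.9) were still called in both, so a part played by length or GC stays open because the intervals span the bound of 80%. Free RNA of 1 compartment, at its marker level in the other, could give 0.5 or more of the knockdown level in 20.3% (13 of 64, interval 11.3 to 32.2), such as Mmp9 (0.726) and Angpt2 (0.659). That count argues against that source for most of the set, as for Dapk3 (0.0547), although its interval also treats the genes as independent. Free RNA from cells of neither compartment would read low by this measure and was not tested. C1qa (0.0747), which macrophages express, read 4.3 CPM in knockdown fibroblasts and 4.5 CPM in knockdown epithelial cells. In 29.7% (19 of 64, interval 18.9 to 42.4) 1 compartment read under 20% of the other, and that interval spans the bound of 25%, so a smaller part from free RNA cannot be told apart from a change in both for the set. An effect of the knockdown on both compartments remains open and untested, as does a difference between the groups in mouse strain, transgenes or AT2 donor, with which the groups are confounded if there was one; Dapk3 and Cebpb rose in every class tested.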

How the results depend on the processing

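The fits with length and GC corrections, without cluster 32, with mixed clusters, limited to genes at 0.5 or more of the other compartment's level, without the highest doublet scores, and all alternatives for the smaller classes and for the share of cycling fibroblasts were chosen after seeing the data.

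Over all results and alternatives 4867 values kept their direction and side of the threshold, moved by less than the spread or, for counts, stayed within 1.5 times, 246 were no longer past the threshold, 185 newly passed, 115 moved further and 3 reversed. The reversals came without cluster 32: Oit1 (-0.027) and Cdh2 (-0.29) in the epithelium and Cdh2 between compartments (0.028), where the removed cells carried both transcripts. In the epithelium 201 genes changed, against 528 with no count filter, 780 with the mixed clusters, 129 without cluster 32 and 113 limited to genes at 0.5 or more of the fibroblast level. In AT2 cells 99 changed, against 27 with DESeq2, 40 with thinned sums, 955 with the mixed clusters and 61 under the same limit. In AT1-like cells 54 changed, against 22 with DESeq2, 146 with no filter, 192 in cells clustered anew and 28 under that limit. Between compartments 610 differed, against 259 with DESeq2, 1303 with no filter, 1010 with the mixed clusters and 95 without the library block. Among fibroblasts only the replicate block and the fits without control library 2 or either knockdown library moved the count of 1860 by more than 1.5 times. Camera with an estimated correlation and fry called 0 of the 9 fibroblast lists (smallest adjusted p = 0.675 and 0.107) and 0 of the 7 epithelial lists (0.881 and 0.218); at an unadjusted p under 0.05 they gave 0 and 5 lists in fibroblasts and 0 and 2 in the epithelium. The difference in AT1-like share was 1.73 points with the mixed clusters against -1.05, and that in AT2 share -2.40 against 5.51. Cycling shares differed by 4.24 points in the epithelium and -8.28 in fibroblasts without thinning, and by 3.12 and -8.19 with at least 2 G2/M genes. The cause of the moves in these counts and shares was not tested.

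Leaving out 1 library at a time, where the lone library of a group is assumed to vary like the other group, gave 998 (without knockdown 2) to 3666 (without control 2) genes in fibroblasts, 136 to 684 in epithelial cells, 40 to 391 in AT2 cells, 15 to 140 in AT1-like cells and 249 to 975 between compartments. The smaller classes gave 493 to 1678 in EMT-like cells, 867 to 1973 in the class deposited as fibroblasts, 189 to 476 and 185 to 437 in inflammatory fibroblasts 1 and 2, 99 to 305 in Myo1f-positive, 538 to 1401 in myofibroblast-like, 71 to 181 in unknown mesenchymal, 55 to 326 in cycling AT2 and 53 to 254 in transitional cells. Cycling fibroblasts gave 0 (without knockdown 2) to 591 with edgeR, the only tool run there, and 2 without knockdown 1; at the 0, 922 genes had an unadjusted p under 0.05. Called lists ranged from 7 to 11 in fibroblasts and 5 to 9 in the epithelium. Differences in share ranged from -10.6 to -2.76 points for fibroblasts, -5.49 to 16.5 for AT2 cells and -2.71 to 0.612 for AT1-like cells.

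The libraries share only a replicate number. Deviations from the group means correlated at 0.371 in fibroblasts and 0.181 in epithelial cells between equal numbers, from 2 pairs. With the replicate block 5820 genes changed in fibroblasts, 329 in the epithelium, 400 in AT2 and 282 in AT1-like cells. In the epithelium the block lost the surfactant lipid and hypoxia lists and gained the inflammatory list. The fibroblast genes split into 2994 higher and 2826 lower, and 19 named fibroblast genes newly passed, Wwtr1 among them (log2 -0.37, adjusted p = 0.0108). The block gave 1379 in cycling fibroblasts, 2386 in EMT-like cells, 3497 in the class deposited as fibroblasts, 512 in inflammatory fibroblasts 2, 2333 in myofibroblast-like, 297 in unknown mesenchymal, 373 in cycling AT2 and 1271 in transitional cells. In simulated data at this depth and replication edgeR recovered 71 of 100 fibroblast and 57 of 100 epithelial genes changed by log2 1, so genes with changes of that size can be missed.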

Other observations

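The tests of lists within single epithelial classes and of the complement and chemokine genes were chosen after the results for the whole epithelium were seen.

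List results within single epithelial classes follow, and differences between classes were not tested. Transitional cells, which carry Krt8 and Cldn4, had lower G2/M genes (median log2 -0.47, camera adjusted p = 5.49e-06, adjusted p = 0.731 with an estimated correlation), with 0 of 17 members passing edgeR, the only tool run there, 5 at an unadjusted p under 0.05 and 2 falls adjusted over the list alone. Free RNA may enter here, as 19 of 24 G2/M genes fell in fibroblasts. The mean share of transitional cells with a UMI of Mki67 or Top2a was 3.53% in controls and 1.69% in knockdowns. In the background class, Myo1f-positive fibroblasts, it was 4.90% and 2.62%. The p53 and senescence genes of transitional cells were higher (median 0.19, adjusted p = 0.00312, adjusted p = 0.731 with an estimated correlation), with 0 of 15 members passing edgeR, 3 at an unadjusted p under 0.05 and 2 adjusted over the list alone. The AT2 genes Cxcl15 and Lyz2 rose in transitional cells, and also in fibroblasts by log2 1.61 and 1.99. AT2 cells had higher S phase genes (median log2 0.20, adjusted p = 0.00475), of which 0 of 23 passed edgeR, DESeq2 or limma voom, with 5, 1 and 4 at an unadjusted p under 0.05, and edgeR gave 1 adjusted over the list alone. They also had higher p53 and senescence genes (0.18, adjusted p = 0.0097), of which Gdf15, a stress-induced cytokine gene, and Igfbp7 passed edgeR. Limma voom called 2 of 14 and DESeq2 0, with 3 at an unadjusted p under 0.05. Igfbp7 also rose in fibroblasts, by log2 1.51, and free fibroblast RNA was not weighed for its rise in AT2 cells. Their YAP/TAZ targets were lower (-0.16, adjusted p = 0.0097), with F3 passing edgeR, while limma voom called 1 of 20 and DESeq2 0, with 1 at an unadjusted p under 0.05; these 3 lists had adjusted p = 0.747 with an estimated correlation. Timp1 fell in AT2, AT1-like and transitional cells, and its fibroblast change was log2 -0.47 (adjusted p = 0.203). Free fibroblast RNA would give 0.672 of the control level of Timp1 in the whole epithelium, so its fall there may be partly one of free RNA.

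Complement and chemokine genes that macrophages express appeared at low, similar levels in both compartments of the knockdown libraries. C1qa and C1qb read 4.29 and 4.43 CPM in knockdown fibroblasts and 4.47 and 3.80 CPM in knockdown epithelial cells, and Ccl6 read 14.7 and 11.4 CPM. All 3 were higher in 2 of 2 knockdown libraries in each compartment, by log2 3.61, 4.49 and 3.96 in fibroblasts (adjusted p = 0.00977, 0.00181 and 0.00207) and 4.79, 5.96 and 4.21 in epithelial cells (0.000229, 0.000349 and 1.64e-05). These genes were picked after their values were seen, and their source was not tested.

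A hypothesis was that the fibroblast changes might only reflect different shares of the deposited classes. The 8 classes with at least 50 cells in every library were given the same weight in every library. The Wnt4-positive, Tgfbi-positive and smooth muscle classes, whose sizes differed most, were left out because some libraries held only 7, 5 and 5 of their cells. Over the 8 classes the 1860 changed genes kept a median share of 0.734 of their log2 fold change (interquartile 0.503 to 0.899) and 98.8% had the same sign. That argues against class shares as the whole cause, though clusters within a class were not weighted. The share kept differed by gene group: Hippo genes that fell kept a median of 0.955 and the risen Wnt ligands and modulators 0.768, with Wnt4 going from 1.39 to 1.00. Fallen S phase and G2/M genes kept 0.40 and 0.242, and Mki67 went from -1.08 to -0.26. Their fall may therefore lie between classes more than within them, although the cycling class is itself defined by such genes.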
